A study of Rattus norvegicus with 6 samples.

How the data were processed

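The series profiled chromatin of PC12 cells, a rat pheochromocytoma line of neural crest origin, by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells stably expressed either the empty pCDNA3 vector or human α1ACT, a transcription factor made from the CACNA1A transcript. The labels title the α1ACT line Q11. Each line gave 3 libraries: one precipitated with the M2 antibody, one with an antibody labelled 1804, and an input. The protocol names M2 as an anti-FLAG antibody, and the labels do not say what 1804 recognises. The series design text speaks of tissues collected at day 3, whereas all 6 sample labels name PC12 cells at passages 18 to 20. Cells were crosslinked with 1% formaldehyde for 10 min. Each of the 6 groups holds 1 library, so no value below has a replicate error and no p-value is given between conditions.

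The authors deposited 1 peak list for each of the 4 precipitated libraries and 1 annotated table for the whole series. No peak list of an input was used here. The deposited lists have the columns of the narrowPeak format. Their names point to the spp peak caller; its version and settings, and whether the inputs served as its controls, are not given in the sources used here. The submitters' processing notes name the rat build rn5, FastQC 0.11.2, BWA 0.7.5a, DiffBind, ChIPseeker and HOMER, without saying what each did. All coordinates below are those of the deposited files, on rn5, written 1-based. The signal column is the authors' own value per peak, and how it was scaled between libraries is not stated. It is used below only to rank peaks within a list, apart from comparisons between lists in the closing section. The lowest −log10 q-value the authors deposited was 1.30 in the empty-vector 1804 list, 1.32 in the empty-vector M2 list, 1.33 in the α1ACT 1804 list and 1.51 in the α1ACT M2 list, and the p column was not filled. Every peak in all 4 lists was 56 bp wide. The annotated table, deposited by the authors, names for each peak the nearest gene, the feature it lies in and its signed distance to the transcription start site (TSS) in bp. Its column names are those of ChIPseeker, which the submitters' processing notes list. The read depth of the libraries is not in the files used here and is therefore unknown.

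Peak lists were compared by overlap of at least 1 bp. Chance overlap was taken from 10000 random circular shifts of the shorter list along each chromosome, whose length was taken as the highest peak end in any list. Peaks within 1000 bp of the TSS in the authors' annotation were called near a TSS. For the other lists and for windows of 1 Mb, TSSs were those named in the authors' table, which holds only genes with an assigned α1ACT-only peak. The windows and the split by side of the TSS were chosen after seeing the data. Intervals on shares are exact 95% binomial intervals (Clopper-Pearson). They cover counting error only, since neighbouring peaks are not independent and the libraries have no replicates. Where a count was 0, the limit is that of 3 counts.

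Gene groups were compared with 21 lists fixed before the data were examined, 19 written by symbol and 2, the olfactory and vomeronasal receptors, by symbol pattern. Of 631 listed symbols, 3 were not matched. The background was the 18539 protein-coding genes with a curated RefSeq transcript in a gene table of assembly GRCr8, from which only names and gene IDs were used; 14269 of the 14390 genes in the authors' table matched it by gene ID. For each list the share of genes with an α1ACT-only peak near the TSS was placed among 10000 random lists of the same size, as a percentile that describes this library. A list at or above the 97.5th or at or below the 2.5th percentile was called above or below chance. Matching on gene length was planned for the main comparison, but lengths on the authors' build were known only for genes that had a peak, so it was run as an alternative over those 13854 genes, in 10 length bins. The same genes were also compared without length matching, a setting chosen after seeing the data, since the restriction alone raises the share with a peak near the TSS from 32.9% to 44.0%. Genes that the authors' annotation did not hold count as without a peak.

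Named genes followed a rule fixed before the data were examined: the genes reported as α1ACT targets with the host gene Cacna1a, the 10 genes with the highest-signal peak near a TSS, the 5 genes with the most assigned peaks, in each fixed list the 2 members with the highest-signal peak near the TSS, the sites present in both α1ACT lists and neither empty-vector list, and the 3 highest-signal peaks of each empty-vector list. Placeholder symbols were skipped, and 3 genes that the rule selects are not reported here. The alternatives tried were merged peaks, stricter signal limits, other overlap rules, other TSS distances, length matching and, chosen after seeing the data, lists without the mitochondrial genome, a shortened longest list, a signal limit taken from the other lists, the lower 50% by signal and pooled gene lists without ribosomal protein genes. The planned comparison of sequence under the peaks was not run, because no genome of the authors' build was used here. The procedures were tested on simulated data. The overlap step found 100 of 100 planted overlaps among 200 peaks. The planted peaks were exact copies, so this does not test partial overlaps. For lists of 40 genes drawn from 18539 with a background share of 30%, the gene list step called 97 of 100 simulated lists with a 2-fold higher share and 2 of 100 with an unchanged share. Only calls above chance were counted in this simulation. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.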

Results

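ChIP-seq peak lists were compared between PC12 cells that stably express human α1ACT and PC12 cells that carry the empty vector, each precipitated with the M2 antibody and with the antibody labelled 1804. The comparison asks where α1ACT, the transcription factor encoded within CACNA1A, lies on chromatin. A site of the introduced α1ACT should be listed in α1ACT cells and not in empty-vector cells. This assumes that no α1ACT of the empty-vector cells themselves is precipitated. Whether that holds is unknown, since the labels do not say what 1804 recognises. Each of the 4 lists came from 1 library, so differences between lists have no replicate check. The read depth of the libraries is unknown.

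The α1ACT 1804 list stood apart from the others in length. It held 161730 peaks, against 272 in the empty-vector 1804 list, which is 595 times as many. With M2 the order was the opposite: 81 peaks were listed in α1ACT cells and 244 in empty-vector cells, 3.01 times as many in the empty-vector line. At 56 bp per peak, the α1ACT 1804 list covered 9056880 bp, the α1ACT M2 list 4536 bp, the empty-vector 1804 list 15232 bp and the empty-vector M2 list 13664 bp. Within the α1ACT 1804 list the authors' signal ran from 2.00 to 899 with a median of 3.03, and 99% of its peaks lay below 9.73. The signal ran from 14.0 to 788 in the empty-vector 1804 list (median 44.6), from 19.0 to 377 in the empty-vector M2 list (median 57.2) and from 53.6 to 371 in the α1ACT M2 list (median 115). How the signal was scaled between libraries is not stated, so it is used below only to rank peaks within a list.

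**Figure D1:**
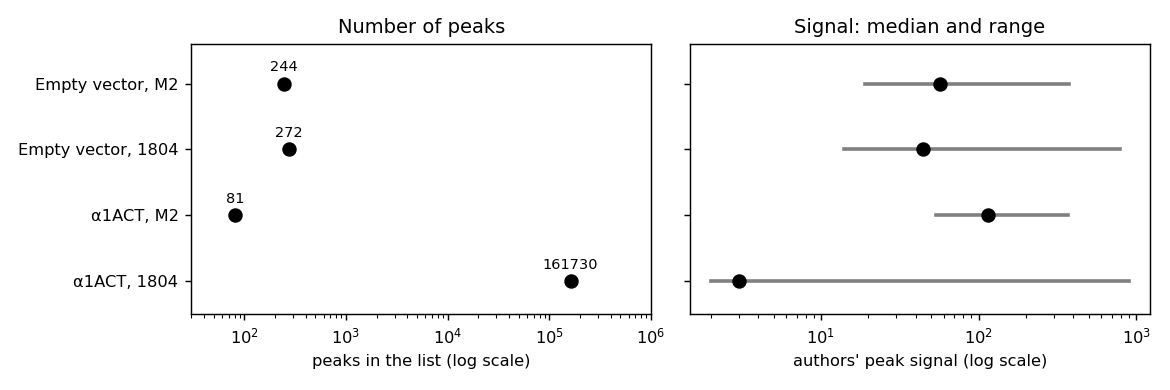
The left panel plots the number of peaks in each of the 4 lists on a log axis, and the right panel the authors' peak signal on a log axis, with the median as a point and the range as a line. The α1ACT 1804 list has 161730 peaks and a median signal of 3.03; signals are the authors' and may be scaled differently between lists.

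The short lists held largely shared sites. Of the 81 α1ACT M2 peaks, 73 overlapped an empty-vector 1804 peak (90.1%, 95% interval 81.5 to 95.6) and 70 an empty-vector M2 peak (86.4%, 77.0 to 93.0), and 69 were found in all 4 lists. Within the empty-vector line, 203 of the 244 M2 peaks were also in the 1804 list (83.2%, 77.9 to 87.7). Within the α1ACT line, 73 of the 81 M2 peaks were in the 1804 list (90.1%, 81.5 to 95.6). The α1ACT 1804 list held 149 of the 244 empty-vector M2 peaks (61.1%, 54.6 to 67.2) and 179 of the 272 empty-vector 1804 peaks (65.8%, 59.8 to 71.4). All 6 overlaps were above each of 10000 random shifts, the highest of which reached 4.94% for the α1ACT M2 peaks in the α1ACT 1804 list. The shared sites were those of highest signal in the α1ACT 1804 list, a comparison chosen after seeing the data. Of its 50 highest peaks, 49 overlapped an empty-vector peak, as did 96 of its 100 highest (96.0%, 90.1 to 98.9). The numbers were 161 of its 272 highest (59.2%, 53.1 to 65.1), 176 of its 1000 highest (17.6%) and 191 of its 10000 highest (1.91%, 1.65 to 2.20). In all, 194 of its peaks overlapped one, which limits the share in the longer sets.

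**Figure D2:**
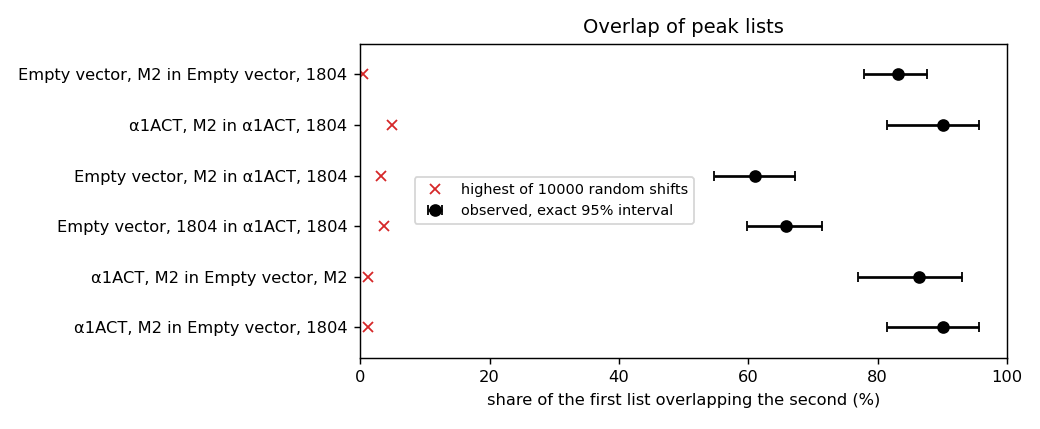
Points give the share, in percent, of the peaks of the first-named list that overlap the second by at least 1 bp, with exact 95% binomial intervals; crosses give the highest share in 10000 random shifts. Observed shares lie between 61.1% and 90.1%, and no cross lies above 4.94%.

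None of the 3 highest-signal sites of either empty-vector list lay within 1000 bp of a listed TSS. In the 1804 list they were chromosome 7 from 142709080 to 142709135, with a signal of 788 and the nearest listed gene TSS, that of Zfp385a, 30.3 kb away; chromosome 2 from 208470940 to 208470995, with a signal of 542 and 14.3 kb from the TSS of Adar, an RNA-editing enzyme; and chromosome 9 from 45204 to 45259, with a signal of 528, within Efhb and 2.26 kb from its TSS. In the M2 list they were chromosome 13 from 38696185 to 38696240, with a signal of 377 and 686 kb from the TSS of Tsn; the same chromosome 7 site, with a signal of 330.0; and chromosome 20 from 42152370 to 42152425, with a signal of 303, within Hs3st5 and 182 kb from the nearest TSS listed for it. The chromosome 7, chromosome 2 and chromosome 13 sites were in both empty-vector lists and in neither α1ACT list. None of 243 empty-vector M2 peaks on the chromosomes lay within 1000 bp of a listed TSS, which allows a share of up to 1.23%, and 2 of 272 empty-vector 1804 peaks did (0.735%, 0.0892 to 2.63). The α1ACT M2 list had 0 of 74, which allows up to 4.05%. Listed TSSs are those of genes with an assigned α1ACT-only peak, so peaks near other TSSs were not counted.

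A single chromosomal site was present in both α1ACT lists and in neither empty-vector list. It lay on chromosome 10 from 110277977 to 110278032, in intron 13 of 38 of Tbcd, the gene of a tubulin-folding cofactor, and had the highest signal of both α1ACT lists, 371 with M2 and 899 with 1804. The nearest empty-vector peak was 514 kb away. Of the 81 α1ACT M2 peaks, 8 (9.88%, 4.36 to 18.5) were in neither empty-vector list. Besides the Tbcd site these were 7 peaks on the mitochondrial genome, with signals of 58.0 to 302. Of the α1ACT 1804 peaks, 161536 (99.9%) were in neither empty-vector list. The authors' annotated α1ACT-only table held 159452 peaks. Each was a peak of the α1ACT 1804 list and none overlapped an empty-vector peak. The 2278 peaks of the list that the table left out were 194 that overlapped an empty-vector peak and 2084 in no empty-vector list, all of which lay beyond the first or last annotated peak of their chromosome.

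Most α1ACT-only peaks lay far from genes, but more lay near a TSS than in random shifts. Peaks near a TSS were of higher signal. In the authors' annotation, 118896 of the 159452 peaks (74.6%, 74.4 to 74.8) were distal intergenic, 25847 (16.2%) intronic, 12206 (7.65%) in promoters, 1458 (0.914%) in exons and 395 (0.248%) in 3' UTRs. The median distance to the nearest TSS was 119026 bp. Within 1000 bp of a TSS lay 9175 peaks (5.75%, 5.64 to 5.87). Counted by the TSSs named in the annotated table the share was 5.71%. In 100 random shifts it had a mean of 1.03% and reached 1.11% at most. Among peaks below the median signal the share was 2.73%, against a mean of 1.00% and at most 1.11% in shifts. In the highest of 10 bins by signal it was 21.3%, against 1.09% and at most 1.34%. The shares in shifts may be too low. Only TSSs of genes with an assigned α1ACT-only peak were counted, and shifted peaks can fall in long stretches without any peak. The median signal was 4.36 near a TSS and 2.99 elsewhere. By signal, the share near a TSS was between 2.09% and 3.89% in each of the 6 lowest of 10 bins of equal size, 8.68% (8.25 to 9.13) in the ninth and 21.3% (20.7 to 22.0) in the highest. Of the peaks near a TSS, 6115 (66.6%) lay over or downstream of it and 3060 (33.4%) upstream. The stretch from the TSS to 100 bp downstream held 1671 peaks, those over the TSS included, and the 100 bp upstream held 680.

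**Figure D3:**
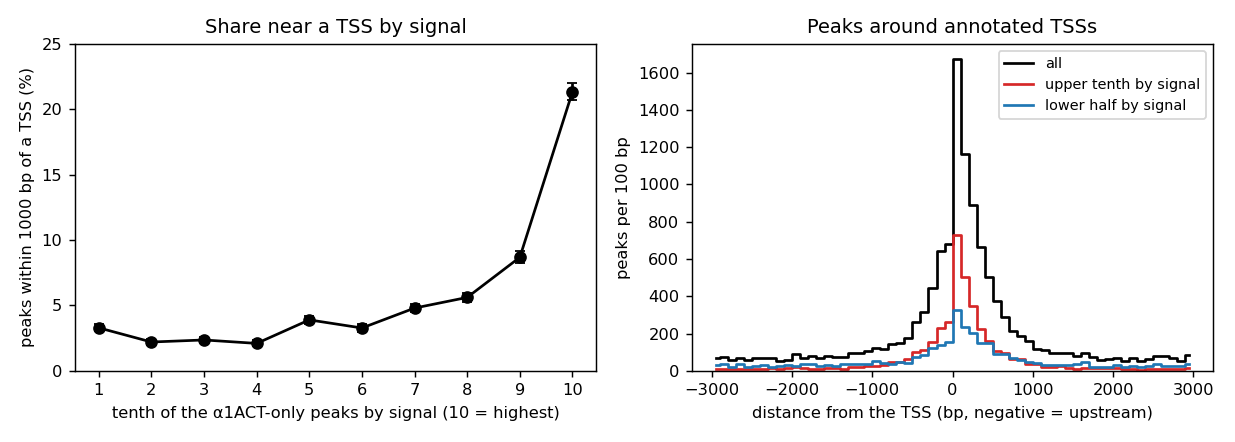
The left panel gives the share of α1ACT-only peaks within 1000 bp of a TSS, in percent, for each of 10 bins of the peaks by signal, with exact 95% binomial intervals. The right panel counts peaks per 100 bp of distance from the annotated TSS for all peaks, the upper 10% and the lower 50% by signal; the tallest bin, which includes peaks over the TSS, holds 1671 peaks.

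Peaks of low and high signal were spread differently over the chromosomes. Over 2893 windows of 1 Mb, the number of peaks in the upper 10% by signal went with the number of listed TSSs (Spearman's rho 0.43, bootstrap 95% interval over chromosomes 0.33 to 0.52), whereas the number in the lower 50% did not (rho -0.09, -0.21 to 0.06). These relations are across windows of 1 library, which are not replicates, and TSSs of genes without an assigned peak were not counted. Windows with a peak but no listed TSS held a mean of 37.0 peaks of the lower 50% and 4.62 of the upper 10%, and windows with 10 or more TSSs held 27.7 and 10.5. Of the 5 genes with the most assigned peaks, each had 87.3% or more of them outside the gene. Cntnap5b, a neurexin-family gene on chromosome 13, was assigned 717 peaks over 7.59 Mb, of which 87.3% lay outside the gene. The vomeronasal receptor gene Vom2r57 was assigned 683 over 4.06 Mb, the olfactory receptor gene Olr1065 539 over 11.3 Mb and the cadherin gene Cdh10 499 over 5.28 Mb. The 522 peaks of the vomeronasal receptor gene Vom1r21 lay closer together, within 1.21 Mb of chromosome 19.

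Of the genes earlier reported as α1ACT targets, Btg1 and Grn had a peak near the TSS in the α1ACT 1804 list and Atp2b2 did not. Of 74 α1ACT M2 peaks on the chromosomes, 0 lay near a listed TSS. The lowest signal in the other lists was 14.0, above that of each Btg1 and Grn peak near the TSS. The scale between lists is not stated, so absence from the empty-vector lists cannot show that these peaks depend on α1ACT. Nor can the list show that α1ACT is absent from the Atp2b2 TSS. Btg1, an antiproliferative gene, had 4 peaks within 1000 bp of its TSS. The highest, on chromosome 7 from 37858528 to 37858583 and 262 bp downstream of the TSS, had a signal of 10.1, above 99.2% of the α1ACT-only peaks. Grn, which encodes progranulin, had 1, on chromosome 10 from 90165694 to 90165749, with a signal of 4.02. That was above 77.1% of the α1ACT-only peaks but below the median signal of 4.36 for peaks near a TSS. Atp2b2, which encodes the plasma membrane calcium pump PMCA2, was assigned 4 peaks. The highest lay on chromosome 4 from 209153836 to 209153891, in intron 18 of 20, with a signal of 3.32, and the nearest to the TSS was 40371 bp upstream. Cacna1a, which holds the α1ACT coding sequence, was assigned 7 peaks, none nearer to the TSS than 15521 bp. The highest, 57148 bp upstream on chromosome 19 from 36445385 to 36445440, had a signal of 6.50. With 2 of 4 genes carrying a peak near the TSS (50.0%, 6.76 to 93.2), this list lay at percentile 75.0 of random lists. The random range for 4 genes ran from 0 to 75.0%, so the list is too short to decide whether its share differs from chance. It includes Cacna1a as the host gene and not as a reported target. The list was drawn up from earlier work and not from these libraries.

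The highest-signal promoter peak belonged to Cadm1, a synaptic cell adhesion gene, on chromosome 8 from 50460979 to 50461034 and 282 bp downstream of the TSS, with a signal of 30.3. Cep95, a centrosomal protein gene, followed on chromosome 10 from 94733463 to 94733518 with 27.3, and Socs2, a suppressor of cytokine signalling, on chromosome 7 from 36561292 to 36561347 with 24.0. Next were the amino acid transporter Slc7a8 with 22.8, the autophagy kinase Ulk2 with 21.5, Lrrc16b with 21.2, Cyb5b, a cytochrome b5 of the mitochondrial outer membrane, with 21.1, Tsc22d2 with 21.1 and the cation channel Trpc1 with 20.3. The class I histocompatibility gene RT1-CE4 had 19.9. It belongs to a multigene family whose members can share reads, so its peak is uncertain.

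Of the 18539 background genes, 6096 (32.9%) had an α1ACT-only peak within 1000 bp of the TSS, and 7 of the 21 fixed lists lay above chance. When only the 13854 genes with an assigned peak were compared, of which 44.0% had a peak near the TSS, 3 lists did, with or without matching on gene length. Immediate early genes led: 22 of 30 (73.3%, 54.1 to 87.7) had such a peak, where the middle 95% of random lists had 16.7 to 50.0%. They were led by the AP-1 subunit Jund, with a signal of 19.5, and the phosphatase Dusp1, with 15.6. Cytosolic ribosomal protein genes followed with 38 of 63 (60.3%, 47.2 to 72.4), among them Rps27 with a signal of 11.0; many genes of this family have near-identical processed copies. Of the oxidative phosphorylation genes, 29 of 51 (56.9%) had a peak near the TSS, led by Ndufv2 with 17.6 and Ndufb7 with 15.4. Among genes with an assigned peak these 3 lists lay at percentiles 100, 100 and 99.7 with length matching. The oxidative phosphorylation list was no longer above chance in the upper 10% by signal (percentile 81.6) or when any assigned peak counted (89.8).

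The other 4 lists above chance were not so among genes with an assigned peak, a restriction that ended these calls without length matching. Of these, the calcium and apoptosis lists only reached the upper end of the middle 95% of random lists. Presynaptic release genes had a peak near the TSS in 21 of 40 (52.5%), led by Rims2 with a signal of 12.2 and Cadps with 12. They lay at percentile 99.5, or 94.0 among genes with a peak and 97.3 within 3000 bp. The percentile was 87.0 in the upper 50% by signal and 80.3 in the upper 10%, but 99.955 for any assigned peak. Calcium channels, pumps and release genes had 19 of 39 (48.7%), led by Calm2 with 16.9 and Cacna2d1 with 12.6, at percentile 98.0, or 85.5 among genes with a peak and 96.2 within 3000 bp, but 99.5 in the upper 50% by signal, 99.3 in the upper 10% and 99.6 for any assigned peak. Cell cycle genes had 20 of 40 (50.0%), led by Mki67 with 6.84 and Mcm7 with 6.74, at percentile 98.6. The list lay at 92.0 among genes with a peak, 34 in the upper 10% by signal and 97.4 for any assigned peak. It stayed above chance within 3000 bp (99.99) and in the upper 50% by signal (98.3). Apoptosis and survival genes had 17 of 34 (50.0%), led by Mdm2 with 11.3 and Diablo with 8.19, at percentile 98.0. They lay at 88.7 among genes with a peak and 93.7 within 3000 bp. The percentile was 92.2 in the upper 50% by signal and 90.7 in the upper 10%, but 99.1 for any assigned peak.

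Markers of the Purkinje cell, the output neuron of the cerebellum, were below chance: 4 of 29 (13.8%, 3.89 to 31.7) had a peak near the TSS. The highest were those of Id2, with a signal of 8.32, and the glutamate transporter Slc1a6, with 4.22. The list lay at percentile 1.11, and at 0.66 among genes with an assigned peak, but it was not below chance within 3000 bp (4.14), in the upper 10% by signal (3.08) or when any assigned peak counted (55.3). Granule cell and cerebellar progenitor genes had 7 of 30 (23.3%), at percentile 13.3, or 1.08 among genes with an assigned peak; Mab21l1 led with 9.17 and Gli1, an effector of hedgehog signalling, had 7.49. Neurogenesis factors had 13 of 40 (32.5%), with Hes6 at 15.1 and Id1 at 12.6, and axon guidance genes 12 of 39 (30.8%), with Unc5c at 12.7 and Ntn1 at 11.3. Postsynaptic genes had 15 of 40 (37.5%), with Gphn at 7.67, and potassium and sodium channels 15 of 37 (40.5%), with Kcnn3 at 15.4 and Kcnq5 at 6.80. Chromaffin and sympathetic markers, the cell type nearest to PC12 cells, had 15 of 32 (46.9%, 29.1 to 65.3), at percentile 94.9, with Phox2a at 9.74. None of these 6 lists from granule cell to chromaffin genes was outside the random range over all background genes.

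Lists of immune, liver, muscle and keratin genes and of chemosensory receptors were below chance, and glial markers were not. No microglia, macrophage or lymphocyte marker of 20 had a peak near the TSS (0%, which allows up to 15.0%). Liver genes had 2 of 20 (10.0%), Fgg and Apoc3, with signals of 3.36 and 3.18, and muscle and keratin genes 2 of 20, Actn2 and Tnni3, with 4.86 and 2.79. Olfactory receptors had 47 of 1197 (3.93%, 2.90 to 5.19), with Olr232 at 5.66 and Olr936 at 5.47, and vomeronasal receptors 6 of 139 (4.32%, 1.60 to 9.16), with Vom1r35 at 8.46 and Vom2r55 at 5.37; both are multigene families in which reads can be shared. The liver call was lost within 3000 bp (percentile 3.70), in the upper 50% by signal (4.04) and for any assigned peak (49.2), the muscle and keratin call within 3000 bp (19.8) and for any assigned peak (7.36), and the immune call for any assigned peak (7.63). For any assigned peak the vomeronasal receptors were above chance, at percentile 100. Astrocyte and oligodendrocyte markers had 7 of 20 (35.0%), within the random range, with Mbp at 8.33 and Fgfr3 at 5.86.

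**Figure D4:**
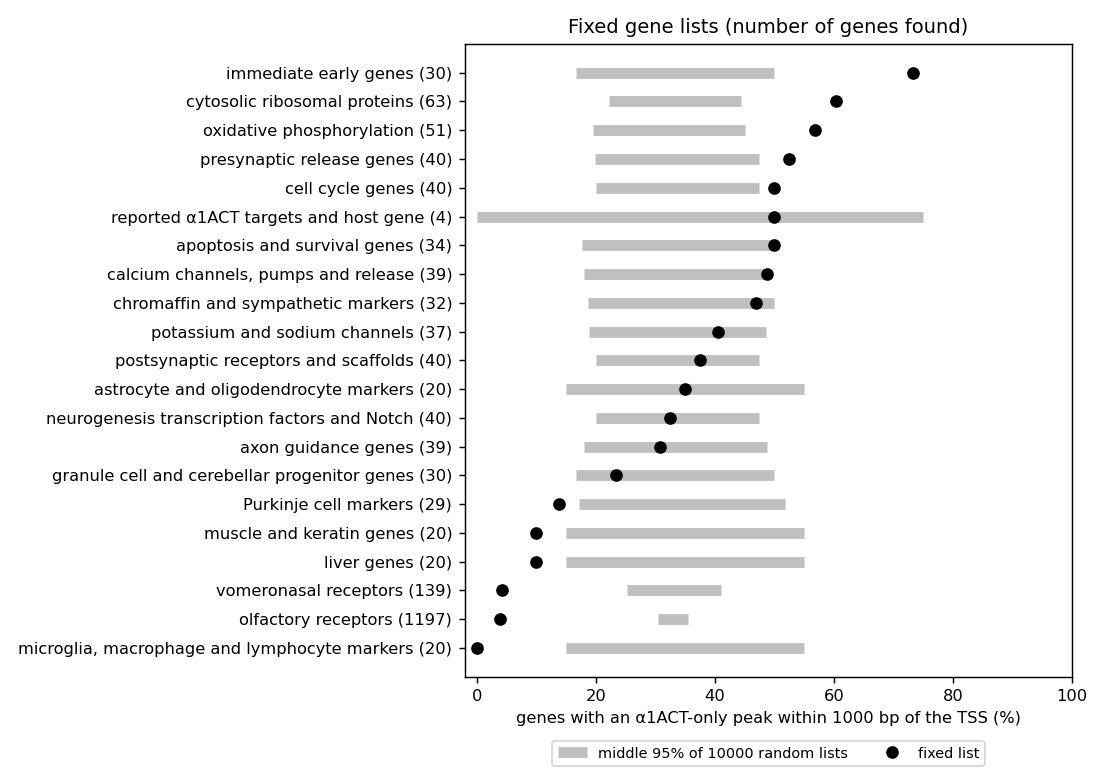
Points give, for each of the 21 fixed gene lists, the percent of genes with an α1ACT-only peak within 1000 bp of the TSS; grey bars span the middle 95% of 10000 random lists of the same size, without length matching. Immediate early genes (73.3%) and ribosomal protein genes (60.3%) lie above their bars and Purkinje cell markers (13.8%) below, while calcium (48.7%) and apoptosis genes (50.0%) lie at the upper ends of theirs.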

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

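Both tests and the check of scale in this part were chosen after the peak numbers had been seen. The α1ACT minus empty-vector difference in the number of peaks went in opposite directions with the 2 antibodies: it was -163 with M2 and 161458 with 1804. With 1 library per group this difference was not tested.

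A candidate explanation for the long α1ACT 1804 list is that peaks were called there at lower signal: 99.7% of its peaks lay below the lowest signal in any other list. The scale between lists is not stated. At the 179 peaks shared with the empty-vector 1804 list, the signal ratio had a median of 1.19 and a 5th percentile of 0.412. Each limit was then multiplied by the 5th percentile of the list's ratios, which lowered the limits of the empty-vector lists only. Even so, 92.8% or more of the peaks lay below. These shares follow from the signal ranges of the lists, and α1ACT at many sites of lower signal would give them too. They therefore do not decide the explanation. Whether read depth, the input or a caller setting lay behind the lower signal cannot be read from the files. If α1ACT lay at the 1804 sites and either antibody brought it down, most α1ACT M2 peaks might be absent from the empty-vector lists. Of these peaks, 90.1% (95% interval 81.5 to 95.6) were present there. This share cannot decide the question, because the α1ACT M2 list began at a signal of 53.6. Only 117 α1ACT 1804 peaks (0.0723%) reached that signal. For this list the 5th percentile of the ratios was 1.04, so the scaled limit was not lower, and 99.9% lay below it. Most 1804 sites could thus be missing from the M2 list with or without α1ACT. A failed M2 precipitation would also give this share, so with 1 M2 library per line an absence of α1ACT at the 1804 sites was not shown.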

How the results depend on the processing

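Counts and shares that changed little under the alternatives are not listed: 38 of the 61 alternative values for the main results stayed within the 95% interval of a share or 1.5 times a count, and 92 of 126 for single gene lists left the list on the same side of chance, although its percentile could move far. Keeping the upper 50% by signal left 122 peaks in the empty-vector M2 list, 136 in the empty-vector 1804, 41 in the α1ACT M2 and 80879 in the α1ACT 1804 list, by construction. The next settings on overlap and α1ACT-only peaks were chosen after seeing the data, except the 1000 bp rule. Without the mitochondrial genome, the share of α1ACT M2 peaks in the α1ACT 1804 list was 98.6%, in the empty-vector 1804 list 98.6% and in the empty-vector M2 list 94.6%, and its α1ACT-only peaks numbered 1 in place of 8; they numbered 5 when no empty-vector peak was allowed within 1000 bp. With the longest list reduced to 272 peaks, it held 54.5% of the empty-vector M2 and 56.6% of the empty-vector 1804 peaks. Its α1ACT-only peaks numbered 317 at or above the lowest signal of the other lists, whose scale can differ. The share near a TSS was 7.65% within 3000 bp, 4.54% within 500 bp, 8.74% in the upper 50% by signal, 21.3% in the upper 10% and, chosen after seeing the data, 2.77% in the lower 50%. Of the gene lists, 7 were above chance and 6 below; 4 and 3 were within 3000 bp, 3 were above in the upper 10% by signal, 3 were above with length matching among genes with an assigned peak and 3 among those genes without matching, a setting chosen after seeing the data, and 9 were above and 1 below when any assigned peak counted. Under that last rule the vomeronasal receptors moved from below chance to percentile 100, granule cell genes from 13.3 to 99.98, postsynaptic genes from 73.3 to 100 and potassium and sodium channels from 83.5 to 99.9, while oxidative phosphorylation was at 89.8; the cause was not tested. The pooled neural minus active difference, -23.5 percentage points near a TSS, was then 4.38, or 4.83 without ribosomal genes, both chosen after seeing the data. The planned sequence comparison and its alternatives were not run for want of a genome. No paired analysis was possible because each group has 1 library. The unknown read depth limits every count, and no list can show that a site is absent.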

Other observations

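The tests in this part on gene families, on the Tbcd site, on pools without ribosomal genes and on pools by signal or any assigned peak were chosen after the data had been seen; those on active and neural genes near a TSS were written before their results. Further gene families, chosen after seeing the data and matched by symbol, fell on both sides of the background share of 32.9%. Chaperonin and DnaJ genes had an α1ACT-only peak within 1000 bp of the TSS in 29 of 54 (53.7%, 95% interval 39.6 to 67.4), translation initiation factors in 26 of 53 (49.1%) and proteasome subunits in 19 of 39 (48.7%), at percentiles 99.9, 99.3 and 97.9 of random lists. Mitochondrial ribosomal proteins (25 of 73, 34.2%), Hox genes (12 of 38, 31.6%), Zfp zinc finger genes (90 of 254, 35.4%) and solute carriers (134 of 364, 36.8%) were within the random range. Protocadherins (7 of 48, 14.6%), keratins (9 of 52, 17.3%), cytochrome P450 genes (9 of 78, 11.5%) and beta-defensins (2 of 39, 5.13%) were below it. The proteasome share only reached the upper end of its random range. All families were compared with all background genes, where genes without an assigned peak count as without one. The median number of assigned peaks was 0 for keratins, 0.5 for protocadherins, 1 for beta-defensins and 5 for cytochrome P450 genes.

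The share of peaks near a TSS was 21.3% in the highest of 10 bins by signal, against 2.09% in the fourth. Near a TSS, genes of neurons and the cerebellum had a peak less often than genes pooled as active. The 6 pooled neural lists had a peak there in 72 of 218 genes (33.0%, 26.8 to 39.7). Ribosomal protein, oxidative phosphorylation and cell cycle genes, pooled as active genes, had one in 87 of 154 (56.5%, 48.3 to 64.5). The difference was -23.5 percentage points (-33.1 to -13.2). Which of these genes were active in PC12 cells was not measured, so the difference cannot tell a preference of α1ACT from gene activity. Among random lists from all background genes the neural pool lay at percentile 52.5. Its lists ranged from 1.11 for Purkinje cell markers to 99.5 for presynaptic genes, so a preference for some neural genes over the background stays open. When any assigned peak counted, the neural minus active difference was 4.38 (-2.37 to 11.7), so the lower neural share did not extend to distant peaks. Open chromatin at active genes is a candidate explanation, since the pooled active genes lay at percentile 100 of random lists. Without ribosomal protein genes 49 of 91 (53.8%) still had a peak near the TSS, and the difference was -20.8 (-32.3 to -8.74). In the upper 10% by signal the difference was -12.9 (-21.3 to -4.65). There the active share of 26.6% rested on ribosomal protein genes (26 of 63). Without these it was 15 of 91 (16.5%, percentile 66.2), and the difference was -2.72 (-12.5 to 5.40). Open chromatin and binding of α1ACT at active promoters therefore both stay open.

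The Tbcd intron site led both α1ACT lists, with signals of 371 and 899, and was in neither empty-vector list. The reverse case was common: 69 of the 203 sites in both empty-vector lists were in neither α1ACT list, with signals of up to 788, among them 2 of the 10 highest of the empty-vector 1804 list. Such sites suggest that high-signal peaks can differ between these lines or their libraries in either direction, so the Tbcd site may be one of them. Binding of α1ACT at this site stays open, as does an effect of α1ACT on the lost sites; neither was tested. The nearest other α1ACT 1804 peak was 11.5 kb away, but the site lay in a stretch of chromosome 10 with many peaks. Its 1 Mb window held 93 α1ACT-only peaks. The windows just before it held 134, 126 and 143, and the window after it 42. Over chromosome 10 the α1ACT 1804 list had 57.7 peaks per Mb. The cause of the higher density, and whether it bears on the signal of the site, was not tested.

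Further α1ACT-only peaks of high signal in the authors' annotated table, singled out after their values were seen, lay on chromosomes 11 and X. They ran from 60846274 to 60846329 on chromosome 11 (signal 143, 49.1 kb upstream of the TSS of Qtrtd1) and from 19832478 to 19832533 on chromosome X (signal 66.9, 63.8 kb downstream of the TSS of RragB). Peaks that this table left out were not ranked with them. Peaks of the α1ACT 1804 list clustered: 37.1% of its α1ACT-only peaks in the lower 50% by signal had another within 1000 bp, against 10.3% when each peak was moved at random by up to 50000 bp, and 18.0% of the upper 10% had another of these, against 3.35%. The mitochondrial genome had 7 peaks in the α1ACT M2 list, 1 in the α1ACT 1804 list, 1 in the empty-vector M2 list and 0 in the empty-vector 1804 list.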
